A study of Mus musculus with 39 samples.

How the data were processed

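Polyadenylated RNA of mouse uterus, uterotubal junction (the narrow passage that joins uterus and oviduct) and oviduct was sequenced, per the labels, as 39 libraries from 13 females of the strain 129SV/S2. In CTR, 5 females were unmated and dissected in the morning in oestrus. In COP, 4 females had copulated with an intact C57/Bl6 male, and in VAS, 4 females had copulated with a vasectomized male, whose ejaculate holds seminal fluid without sperm. Mated females had been paired in the evening, were found with a copulation plug early in the next morning and were dissected 6 to 8 h after copulation. Each female gave 1 library per tissue, and the number of the female in the labels joins its 3 libraries. Tissue was kept in RNAlater, and RNA was extracted with a column kit for the uterus and with the micro version of that kit for the other tissues, so kit and tissue cannot be separated. RNA integrity numbers ran from 6.3 to 9.8, with no value per library in the sources used here. Reads were planned as pairs of 150 bp.

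Per the submitters' processing notes, FastQC, Trim Galore 0.6.7, HISAT2 2.2.1 and StringTie 2.2.1 were used with the mouse genome build GRCm38. Their roles, options and gene annotation, and any use of strand, are not given in the sources used here. The deposited matrix holds estimated counts, read here as the StringTie kind from their values, as whole numbers with no normalization, for 50127 genes and 39 libraries. Low values pile up at multiples of about 3.84, so that 1 sequenced pair of reads was worth about 3.84 counts. Library totals ran from 60806960 to 143333002 counts, which corresponds to about 15800000 to 37300000 pairs.

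The matrix names genes by 2 kinds of identifier. For 24973 genes the name is an assembly identifier of the kind that StringTie gives to merged loci, and these hold 99.83% to 99.93% of all counts in a library. The matrix gives no symbol or coordinates for them, so they enter the tests and counts and are not named. The other 25154 genes carry Ensembl identifiers, 25043 of which matched a symbol in the GENCODE annotation of mouse release 21 on GRCm38, the source of all coordinates given. Of the genes with an Ensembl identifier, 11119 had any count and 2141 reached a mean of 10 counts. Named genes are therefore mostly genes of low level. Whether an unnamed locus covers the same gene as a named one was not tested, so the values of a named gene can hold part of its transcripts.

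Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3. Each tissue was fitted on its 13 libraries with the 3 treatments as groups, and CTR tissues and the tissue by treatment differences on all 39 libraries with 9 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. All adjusted p-values of single genes come from this test unless another tool is named, and each standard error is the log2 fold change divided by the square root of F. Levels are CPM, the counts of a gene relative to the TMM-scaled library total, given as mean ± SD. A fold against a group with 0 counts in every library was computed against a floor of 3 pairs, or 11.5 counts, over the whole group, and is given as a lower bound. Such floors and all intervals cover counting error only.

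Before the data were examined, 40 lists of marker and pathway genes were fixed. Of these, 20 held no tested named gene and only 10 held at least 3 in some tissue. So 28 lists were added after identifiers and total counts were seen and before any groups were compared. Lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, against the other named genes. That background was chosen after a first look at single genes and before any list was tested. Adjustment ran separately over the fixed and the added lists of a comparison, so an adjusted p of a list is always one from camera.

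The genes named were taken by a rule fixed beforehand. Per treatment comparison it takes called genes with at least 1 CPM in the higher group and no overlap between the libraries of both groups, the 6 with the largest fold in each direction. It adds up to 4 called members of each list with the smallest adjusted p, and up to 2 members of highest level where a list is given as not passing. Between tissues it takes 5 genes in each direction, and per tissue by treatment difference the 5 with the smallest adjusted p and 1 CPM in some group. Gene models without a proper name, Y-linked genes, antigen receptor segments and ribosomal pseudogenes were counted and not named, and some genes were left out by rank for length. Some called genes that the rule takes are not reported here. Transcripts of sperm were examined as a check of the labels.

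Within a tissue the treatments hold different females, so no pairing enters the tests. By the labels the same females gave all tissues. Deviations of a female's libraries from their group means, over 12606 genes with a mean of at least 100 counts, had a median correlation of -0.016 between uterus and uterotubal junction, -0.007 between uterotubal junction and oviduct and -0.025 between uterus and oviduct. No libraries of a group were identical. Pairs of libraries of a group differed by 1.73 to 44.63 times counting noise, with a median of 2.015 in VAS uteri. A limma fit over all 39 libraries gave a consensus correlation of -0.035 between the libraries of a female. P-values measure the spread between the libraries of a group only. Whether these libraries hold the full spread between females was not tested, and if they do not, too many genes are called.

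Alternatives were RLE scaling, DESeq2 1.42.0, limma voom with sample weights, no filter and a stricter filter (1 CPM in at least 4 libraries and 50 counts in total), fits of the compared groups alone, the female as a block, each female left out in turn, and for lists an estimated correlation and fry. After the data were seen, counts per pair of reads, the added lists, a list background of every tested gene, the female as a block in list tests between tissues and fits without the uterus library of control female 12 and the oviduct library of control female 10 were added. On simulated counts with 200 changed genes, the test of COP against CTR recovered 53.6% of 4-fold changes in the uterus, 64.8% in the uterotubal junction and 72.2% in the oviduct. It recovered 29%, 47.9% and 62.1% of 2-fold changes, with 6, 3 and 3 false calls among 18453, 17264 and 19382 genes. Tables were prepared with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.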

Results

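The study measured messenger RNA along the female reproductive tract of the mouse after copulation. Uterus, uterotubal junction and oviduct were each sequenced from 5 unmated females in oestrus (CTR), 4 females mated with intact males (COP) and 4 females mated with vasectomized males (VAS). Library totals were 96965984 to 143333002 counts in the uterus, 60806960 to 142342878 in the uterotubal junction and 68860142 to 103719052 in the oviduct. Genes with an Ensembl identifier took 0.076% to 0.148% of the counts in CTR uteri and 0.15% to 0.173% across the 3 groups of oviducts. Counts of genes given for a comparison cover named and unnamed genes, and named genes are mostly of low level.

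The libraries of a group differed in how close they stood. The median distance of a library to the others of its group, in log2 units over abundant genes, was 0.068 to 0.073 in VAS uteri and 0.092 to 0.132 in COP uteri, against 0.49 to 0.848 in CTR uteri. The uterus library labelled control female 12 stood farthest at 0.848, with 18239 genes detected and 15.55% of its counts in its 10 most abundant genes, against 4.23% to 6.83% in the other CTR uteri. The COP uterotubal junctions were alike in these measures, with 18100 to 18438 genes and 14.9% to 15.66%, and that uterus stood 0.633 from COP uteri and 0.695 from COP junctions. Over genes that changed the same way in COP and VAS uteri when it was left out, the uterus of female 12 lay a median 0.833 of the way from the other CTR uteri to the mated uteri. Over genes chosen anew with each library left out in turn, the CTR uterus of female 1 lay 0.433 of the way, and those of females 2, 3 and 10 lay at 0.141, -0.04 and -0.119. Over such genes of their own tissues, the uterotubal junction and oviduct libraries of female 12 lay at 0.019 and 0.11. The CTR uterus of female 10 stood 0.65 from its group and 0.621 from CTR uterotubal junctions, its nearest library being the CTR uterus of female 3 at 0.304. In the oviduct, the library labelled control female 10 stood 0.625 from its group, with 18206 genes detected against 21995 to 22807 in the other CTR oviducts.

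**Figure D1:**
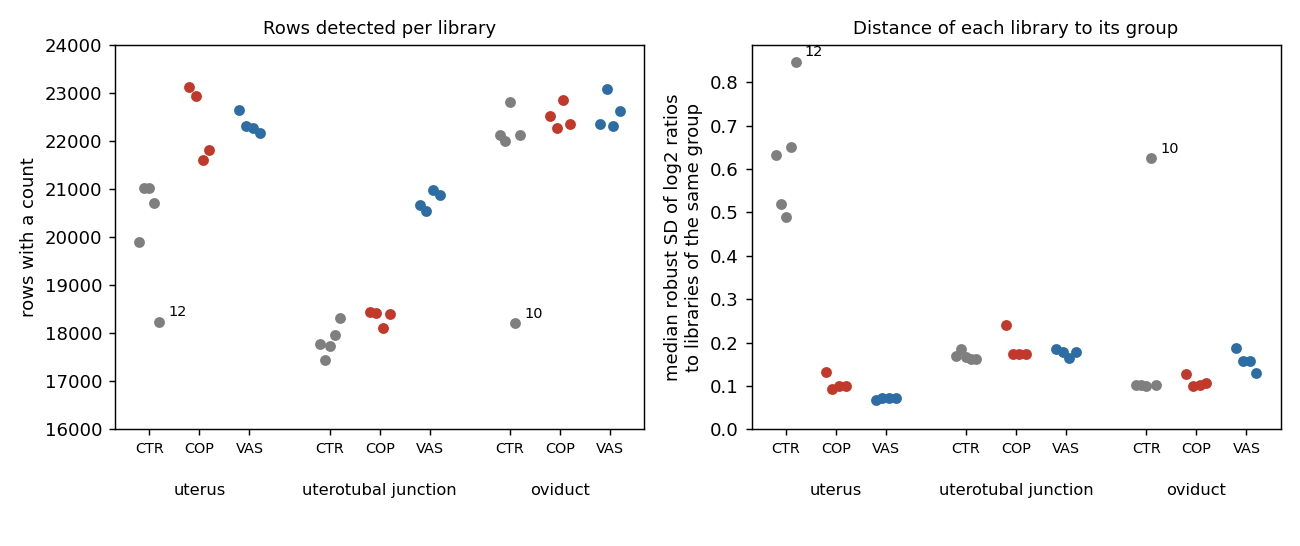
Number of genes detected per library (left) and median distance of each library to the others of its group in log2 units (right), by tissue and treatment, with 1 point per library. The uterus of female 12 (0.848) and the oviduct of female 10 (0.625) stand apart from the other libraries of their groups.

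Transcripts of sperm and spermatids, which an intact male could bring, were examined first as a check of the labels. Of 22 such genes 17 are in the matrix and 15 had any count. Their summed level was 0.237 ± 0.0457 CPM (SD, n = 4) in COP uteri, 0.272 ± 0.174 CPM (n = 4) in VAS uteri and 0.0811 ± 0.051 CPM (n = 5) in CTR uteri. By two-sided exact permutation tests COP against VAS gave p = 0.714 (adjusted over 6 tests 0.857) and COP against CTR p = 0.0159 (adjusted 0.0954). The latter is the smallest p that 4 against 5 libraries can give, with all 4 COP uteri (0.198 to 0.304 CPM) above all 5 CTR uteri (0 to 0.13 CPM). For 4 against 4 the smallest is 0.0286, so that a single difference could not pass after adjustment over 6 tests. In the uterotubal junction the sums were 0.0858 ± 0.138 CPM in COP, 0.372 ± 0.136 CPM in VAS and 0.132 ± 0.19 CPM in CTR. In the oviduct they were 1.36 ± 0.202, 1.18 ± 0.664 and 0.636 ± 0.574 CPM. For COP against VAS and against CTR, exact permutation p-values were 0.0571 (adjusted 0.127) and 0.873 (adjusted 0.873) in the uterotubal junction and 0.6 (adjusted 0.857) and 0.0635 (adjusted 0.127) in the oviduct. The ranges of COP and VAS libraries overlapped in all 3 tissues.

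The comparison of COP with CTR uteri asks which uterine transcripts differ after mating with an intact male. Mmp13, a collagenase of matrix breakdown, rose from 0.0165 ± 0.0239 CPM (SD, n = 5) in CTR to 1.11 ± 0.432 CPM (n = 4) in COP, a log2 fold change of 5.95 ± 0.98 (SE, adjusted p = 0.0013). Casq2, the calsequestrin of heart muscle, rose from 0.439 ± 0.49 to 2.35 ± 0.236 CPM, and C4a, a complement gene whose near-identical copy C4b makes its value uncertain, from 0.602 ± 0.696 to 3.51 ± 0.61 CPM. Reg3g, an antibacterial lectin, rose from 0.062 ± 0.0622 to 0.591 ± 0.121 CPM (log2 fold change 3.24 ± 0.79, adjusted p = 0.0114). Among genes that fell, Tro, which encodes trophinin, went from 3.08 ± 1.57 to 0.321 ± 0.0901 CPM (-3.26 ± 0.45, adjusted p = 0.000462) and Has2, a hyaluronan synthase, from 1.52 ± 0.533 to 0.22 ± 0.0752 CPM (-2.79 ± 0.41, adjusted p = 0.000685). The glutamate receptor gene Grid1 fell from 2.78 ± 1.69 to 0.0681 ± 0.0559 CPM and Vstm2a from 1.39 ± 0.787 to 0.124 ± 0.0384 CPM. Mmp13 (ENSMUSG00000050578) lies on chromosome 9 from 7272514 to 7283331. Tro (ENSMUSG00000025272) lies on chromosome X from 150645304 to 150657583 and Has2 (ENSMUSG00000022367) on chromosome 15 from 56665627 to 56694539.

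Other genes that rose by the largest folds in COP uteri were Cpvl (3.58 ± 1.11), Stum (2.34 ± 0.77) and the small GTPase gene Rasl10b (2.27 ± 0.48), as log2 fold changes with SE. Others that fell were Ajap1 (-5.56 ± 0.99), Minar1 (-4.09 ± 1.09) and Iqsec3 (-3.08 ± 0.69). Of 24 tested genes in the list of neutrophils and activated myeloid cells, 3 rose and 21 did not pass. The list was higher (adjusted p = 0.00396, or 0.285 with an estimated correlation). The risen members were the paired immunoglobulin-like receptor genes Lilra6 (from 0.575 ± 0.277 to 1.92 ± 0.426 CPM) and Pira2 (from 0.384 ± 0.227 to 1.04 ± 0.131 CPM), whose near-identical copies make both uncertain, and Cebpe, a transcription factor of granulocyte maturation (from 0.0634 ± 0.0763 to 0.554 ± 0.139 CPM). The added list of cumulus and granulosa genes was lower (adjusted p = 0.00436, or adjusted p = 0.15 with an estimated correlation), with Has2 and Nr5a2, a nuclear receptor that went from 1.07 ± 0.679 to 0.241 ± 0.104 CPM, called among 3 tested. Zinc finger genes of the Zfp kind were lower too (adjusted p = 0.00436, or 0.358 with an estimated correlation). Of their 33 tested members 6 fell, among them Zfp711 (-1.66 ± 0.35), Zfp786 (-1.51 ± 0.42), Zfp982 (-1.69 ± 0.47) and Zfp641 (-1.4 ± 0.4), and similar copies make such values uncertain.

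None of the 8 fixed lists tested in these uteri was called, against 2 at an unadjusted p under 0.05 and 4 by fry. In the eosinophil and mast cell list, Siglecf, a lectin of eosinophils, rose from 0.0822 ± 0.103 to 0.722 ± 0.271 CPM (log2 fold change 3.13 ± 1, adjusted p = 0.0394), and 2 of its 4 tested members rose when adjusted over the list alone (list adjusted p = 0.0788). Of the fixed cumulus list 2 members fell over all genes and 2 adjusted over the list alone. Slc4a1, the anion exchanger of red blood cells, had no count in any CTR uterus and stood at 0.171 ± 0.133 CPM in COP, at least 9.27-fold higher. In all, 1895 genes were higher and 2499 lower in COP than in CTR among 19535 tested, of which 116 and 83 were among 2249 with names. Without control female 12 the counts were 3824 and 3990. Without COP female 5, 7 or 8 the higher count was 1195, 1249 or 1237, and without 5, 7, 8 or 9 the lower count was 1454, 1517, 1492 or 1573. A fit to both groups alone called 744 higher and 1232 lower, and limma voom with sample weights 4633 and 4614. Omission of a single female ended the calls of Cebpe, Stum, C4a, Siglecf, Cpvl, Zfp641, Zfp786, Zfp982, Pira2 (without 7 or 8), Minar1 and Nr5a2 (both without 5), at adjusted p-values up to 0.0964.

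VAS uteri against CTR uteri show what differs after mating without sperm in the ejaculate. Of 24 tested genes in the neutrophil and activated myeloid list 6 rose and 18 did not pass, with all 24 at a higher mean in VAS. The list was higher (adjusted p = 5.92e-10, or 0.0975 with an estimated correlation). Lilra6 rose from 0.575 ± 0.277 CPM (SD, n = 5) to 2.09 ± 0.37 CPM (n = 4), Pira2 from 0.384 ± 0.227 to 1.27 ± 0.125 CPM, and Cd300lb, an activating receptor of myeloid cells, from 0.817 ± 0.385 to 2.86 ± 0.388 CPM (log2 fold change 1.81 ± 0.4, adjusted p = 0.0084). Treml2 stood at 3.2 ± 0.306 CPM against 0.876 ± 1.06 CPM, and Mmp25, a membrane protease of leukocytes, at 1.34 ± 0.244 against 0.243 ± 0.216 CPM. The interferon-inducible list was higher too (adjusted p = 0.000744, or 0.0975 with an estimated correlation), with 5 of 13 called. Among them were Tlr9, a receptor for unmethylated DNA (from 0.329 ± 0.172 to 1.13 ± 0.274 CPM), Nlrc3 (from 0.394 ± 0.0923 to 0.958 ± 0.447 CPM) and the neighbours Trim30b (log2 fold change 3.8 ± 1.24) and Trim30c (5.22 ± 1.1), which are similar enough to be uncertain. Cd300lb (ENSMUSG00000063193) lies on chromosome 11 from 114922781 to 114934386 and Tlr9 (ENSMUSG00000045322) on chromosome 9 from 106222598 to 106226883.

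Of 37 genes tested in the list of matrix and matrix proteases 10 fell, 1 rose and 26 did not pass, and the list was lower (adjusted p = 0.0259, or adjusted p = 0.44 with an estimated correlation; 0.0574 without female 6). Fbn2, a fibrillin, fell from 5.77 ± 2.72 to 1.86 ± 0.328 CPM (-1.63 ± 0.33, adjusted p = 0.00563), Col24a1 from 1.53 ± 1.12 to 0.16 ± 0.0493 CPM, Adamts17 from 1.38 ± 0.913 to 0.246 ± 0.0964 CPM and Col22a1 from 1.88 ± 2.23 to 0.048 ± 0.0589 CPM. Mmp13 rose from 0.0165 ± 0.0239 to 0.15 ± 0.0497 CPM (3.07 ± 0.91, adjusted p = 0.0326). Has2 fell to 0.529 ± 0.0912 CPM (-1.52 ± 0.39, adjusted p = 0.0163) and Nr5a2 to 0.25 ± 0.0307 CPM. The added cumulus list was lower (adjusted p = 0.0389, or 0.175 with an estimated correlation), a call lost without female 6, 12, 13 or 15 (0.0808, 0.0763, 0.0634 and 0.0544). Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor, fell from 1.46 ± 0.65 to 0.0708 ± 0.0499 CPM (-4.35 ± 0.81, adjusted p = 0.00329).

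The largest other rises in VAS uteri were those of Asz1 (4.92 ± 1.12), a gene of germ cells, Ky (3.26 ± 0.85), the histamine receptor gene Hrh2 (2.74 ± 0.73) and Amer2 (2.62 ± 0.4), as log2 fold changes with SE. Grid1 (-5.91 ± 1.22), Crtac1 (-4.64 ± 1.32), Vstm2a (-4.42 ± 0.8) and Minar1 (-3.89 ± 1.08) fell. In all 1788 genes were higher and 2007 lower in VAS among 19535 tested, with names for 119 and 95. The higher count became 1102 without female 6, 1082 without 13, 1106 without 14, 1102 without 15 and 3565 without control female 12. The lower count became 1062, 1070, 1043, 1069 and 3794. A fit to both groups alone called 779 and 831, voom with sample weights 4404 and 4568, and DESeq2 3017 lower. Single omitted females ended the calls of Trim30b, Treml2, Mmp25, Nlrc3, Mmp13, Col22a1, Crtac1, Minar1, Nr5a2, Has2, Hrh2, Ky and Tlr9 (without 14), at adjusted p-values from 0.0504 to 0.146.

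COP and VAS uteri differ in whether the male was vasectomized. Tmem229a was higher in COP, at 1.47 ± 0.416 CPM (SD, n = 4) against 0.325 ± 0.0827 CPM (n = 4), a log2 fold change of 2.17 ± 0.33 (SE, adjusted p = 0.013). Amer2, an adaptor of Wnt signalling, was lower at 0.251 ± 0.0635 against 1.27 ± 0.0866 CPM (-2.33 ± 0.43, adjusted p = 0.0333). These were the 2 named genes called. Mmp13 at 1.11 ± 0.432 against 0.15 ± 0.0497 CPM (adjusted p = 0.227) and Has2 at 0.22 ± 0.0752 against 0.529 ± 0.0912 CPM (adjusted p = 0.235) did not pass. The fit shares its spread with the more scattered CTR uteri, so a missed call does not show likeness. The neutrophil and activated myeloid list was lower in COP (adjusted p = 3.21e-07, or 0.357 with an estimated correlation), with 22 of 24 means lower. Of the 24 edgeR called 0 (4 lower at an unadjusted p under 0.05), DESeq2 0 and voom with sample weights 15 lower and 1 higher.

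In all 37 genes were higher and 53 lower in COP than in VAS uteri among 19535 tested. Without control female 12, 1 or 2 the counts were 337 and 707, 123 and 168, or 82 and 83, and without control female 10 the higher count was 67. Without any 1 of the 8 mated females 6 to 9 were higher and 12 to 17 lower. DESeq2 called 244 and 409, a fit to COP and VAS alone 3805 and 4098 and voom with sample weights 3780 and 4008. No filter gave 23 higher and a stricter one 81 lower. The call of Amer2 ended without any 1 of the mated females and that of Tmem229a without 6, 7, 9, 13, 14 or 15 (adjusted p from 0.0527 to 0.157).

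**Figure D2:**
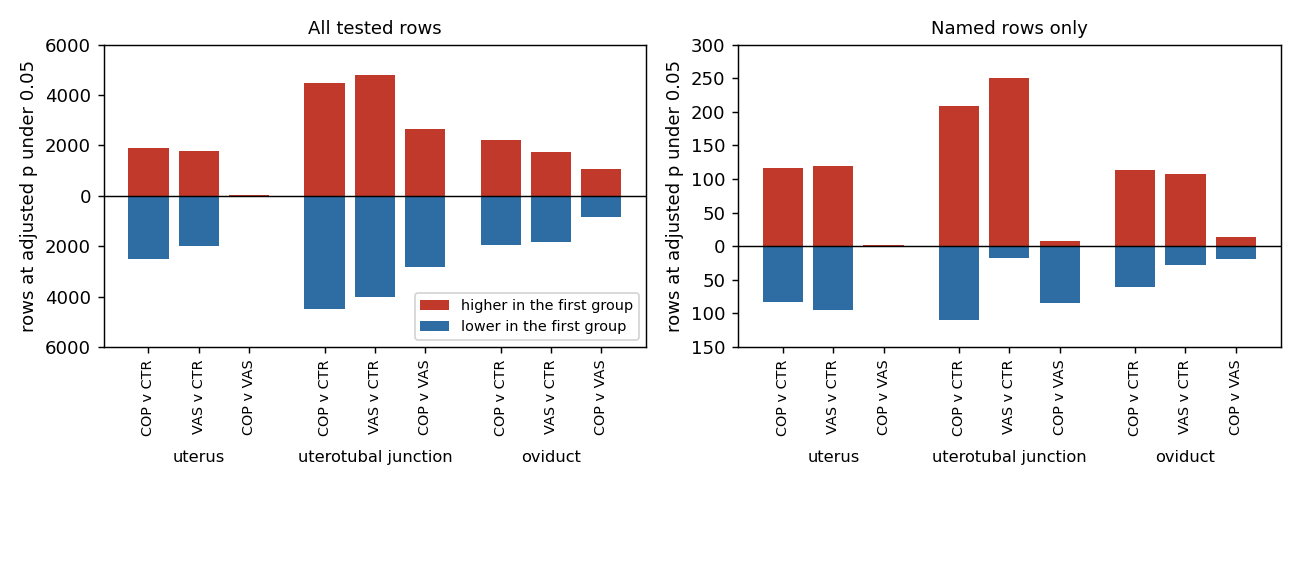
Number of genes called higher (above 0) and lower (below 0) per treatment comparison in each tissue, by the edgeR test. The uterotubal junction has 4461 higher and 4483 lower in COP against CTR, and the uterus has 37 and 53 between COP and VAS, or 3805 and 4098 in a fit to COP and VAS alone.

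In the uterotubal junction, COP against CTR gave a fall in Has2, which had no count in any COP library against 1.15 ± 0.655 CPM (SD, n = 5) in CTR, at least 44-fold lower (adjusted p = 1.1e-05). Trank1 rose from 0.332 ± 0.219 to 4.53 ± 0.878 CPM (n = 4), a log2 fold change of 3.77 ± 0.57 (SE, adjusted p = 3.64e-05), and Slc10a2, a bile acid transporter, from 0.128 ± 0.118 to 1.81 ± 0.668 CPM. Cd86, a costimulatory molecule of antigen-presenting cells, rose from 0.41 ± 0.252 to 1.73 ± 0.59 CPM (2.08 ± 0.54, adjusted p = 0.00401). The antimicrobial Reg3g (0.575 ± 0.374 CPM) and the acute phase gene Saa1 (0.349 ± 0.155 CPM) had no count in CTR and were at least 25.7-fold and 15.6-fold higher. Myocd, a coactivator of smooth muscle genes, fell from 2.27 ± 0.413 to 0.962 ± 0.308 CPM (-1.24 ± 0.32, adjusted p = 0.00437), and Sh3rf3 fell from 4.65 ± 1.27 to 0.754 ± 0.428 CPM. Trank1 (ENSMUSG00000062296) lies on chromosome 9 from 111311739 to 111395775. Cd86 (ENSMUSG00000022901) lies on chromosome 16 from 36603869 to 36666081 and Myocd (ENSMUSG00000020542) on chromosome 11 from 65176561 to 65269989.

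The subunits of the T cell coreceptor CD8 had no count in CTR junctions. Cd8b1 stood at 0.338 ± 0.429 CPM in COP, at least 15.1-fold higher (adjusted p = 0.00277). Cd8a stood at 0.0578 ± 0.116 CPM, at least 2.58-fold higher (adjusted p = 0.0341), a call that rests on COP female 9 alone, since without it the value is 0. Cd209a, a lectin of dendritic cells, had no count in COP and was at least 5.42-fold lower. Other genes that rose were Nav3 (4.86 ± 1.32), Luzp2 (4.06 ± 1.43), Sowaha (3.86 ± 1.07) and the adrenergic receptor gene Adra2b (3.86 ± 1.42). Vstm2a (-3.59 ± 1.2), the M-band gene Myom2 (-3.47 ± 1.28), Nfasc (-2.42 ± 0.93) and Drp2 (-1.96 ± 0.56) fell. No list was called in this comparison by camera, against 5 of 27 added and 0 of 5 fixed lists at an unadjusted p under 0.05 and 18 added lists by fry. Of the 9 tested T and NK cell markers 2 rose over all genes and 1 adjusted over the list alone, and of 7 dendritic cell markers 1 rose and 1 fell either way.

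In all 4461 genes were higher and 4483 lower in COP than in CTR junctions among 18664 tested, with a median absolute log2 fold change of 0.71. Among 1872 named genes 209 were higher, 143 of them with no count in any CTR library, and 110 lower. Libraries of this tissue detected 17447 to 18308 genes in CTR, 18100 to 18438 in COP and 20533 to 20981 in VAS. The 10 most abundant genes took 7.76% to 7.81% of counts in CTR, 14.9% to 15.66% in COP and 10.52% to 10.75% in VAS junctions, and TMM factors were 1.073 to 1.078 in CTR, 0.855 to 0.876 in COP and 1.04 to 1.061 in VAS. Named genes held 0.073% to 0.079%, 0.072% to 0.077% and 0.105% to 0.115% of their counts. The median spread in a group, relative to counting noise, was 8.16 in CTR, 8.52 in COP and 3.54 in VAS. Without 1 female the calls of Nfasc, Cd8a, Adra2b, Myom2 and Luzp2 (without 8) ended, at adjusted p from 0.0503 to 0.108 (except Cd8a without 9).

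VAS junctions against CTR junctions shared several of these genes. Trank1 rose to 5.64 ± 1.03 CPM (SD, n = 4; log2 fold change 4.08 ± 0.58, adjusted p = 1.77e-05), and Cd86 to 1.34 ± 0.229 CPM (1.7 ± 0.53, adjusted p = 0.0142). Cd163, a scavenger receptor of macrophages, rose from 0.863 ± 0.261 CPM (n = 5) to 2.79 ± 0.608 CPM (1.69 ± 0.54, adjusted p = 0.0156, or 0.0544 without female 15). Npas4, an activity-induced transcription factor, had no count in CTR and stood at 1.36 ± 0.307 CPM, at least 60.9-fold higher (adjusted p = 0.0016). Cd8a (0.291 ± 0.0823 CPM), Cd8b1 (0.121 ± 0.0565 CPM) and Reg3g (0.146 ± 0.137 CPM) were at least 13-fold, 5.43-fold and 6.52-fold higher than in CTR, where they had no count. Tacr1, the receptor of substance P, fell from 2.78 ± 1.17 to 0.49 ± 0.135 CPM (-2.5 ± 0.55, adjusted p = 0.00114), and Cyp1a1 from 1.93 ± 0.539 to 0.593 ± 0.383 CPM. Npas4 (ENSMUSG00000045903) lies on chromosome 19 from 4984355 to 4990316 and Tacr1 (ENSMUSG00000030043) on chromosome 6 from 82402334 to 82560104.

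Other rises in VAS junctions were those of Tcp10c (4.06 ± 1.39), the transporter gene Abca6 (3.86 ± 1.13), the kinesin gene Kif1a (3.52 ± 1.37) and Fcer2a (3.5 ± 1.34), a low-affinity receptor for IgE. Vstm2a (-3.7 ± 1.21), Sh3rf3 (-1.76 ± 0.41), Rps6kl1 (-1.7 ± 0.62) and Drp2 (-1.67 ± 0.55) fell. No list was called by camera, against 6 of 27 added and 0 of 5 fixed lists at an unadjusted p under 0.05 and 26 added and 4 fixed lists by fry. Of the T and NK cell markers 2 of 9 rose, also adjusted over the list alone. In all 4788 genes were higher and 4012 lower among 18664 tested, with a median absolute log2 fold change of 0.69. Of the named genes 250 were higher and 18 lower, and 167 of the 250 had no count in CTR, beside the higher number of genes detected in VAS (20533 to 20981). Leaving out 1 female ended the calls of Kif1a, Fcer2a, Rps6kl1, Drp2, Tcp10c and Vstm2a, at adjusted p-values from 0.0502 to 0.0913.

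Between COP and VAS junctions, Has2 differed, with no count in COP and 0.498 ± 0.17 CPM (SD, n = 4) in VAS, at least 19-fold lower in COP (adjusted p = 8.25e-05). Drd1, a dopamine receptor, stood at 0.898 ± 0.439 CPM (n = 4) in COP against 2.62 ± 0.573 CPM in VAS, a log2 fold change of -1.54 ± 0.38 (SE, adjusted p = 0.00497), and Myocd stood at 0.962 ± 0.308 against 2.13 ± 0.305 CPM (-1.14 ± 0.33, adjusted p = 0.016, or 0.0561 without female 15). Cracr2a was lower at 0.0852 ± 0.118 against 1.28 ± 0.342 CPM, Arhgap30 at 2.24 ± 1.16 against 4.74 ± 0.324 CPM and Cd163 at 0.923 ± 0.78 against 2.79 ± 0.608 CPM. Higher in COP were Smarca1, a chromatin remodeller (2.28 ± 0.326 against 0.916 ± 0.203 CPM), and Gria3, a glutamate receptor subunit (4.02 ± 0.823 against 1.73 ± 0.277 CPM). So were Edn3, an endothelin (1.45 ± 0.57 against 0.456 ± 0.137 CPM) and Scube3 (5.31 ± 0.481 against 2.89 ± 0.831 CPM). Cd209a and Ms4a2, the latter part of the IgE receptor of mast cells, had no count in COP and were at least 11.6-fold and 13.8-fold lower. Drd1 (ENSMUSG00000021478) lies on chromosome 13 from 54051183 to 54055705 and Smarca1 (ENSMUSG00000031099) on chromosome X from 47809368 to 47892974.

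In all 2660 genes were higher and 2818 lower in COP junctions among 18664 tested, with a median absolute log2 fold change of 0.5. Of the named genes 7 were higher and 85 lower, and 73 of the 85 had no count in COP libraries, which detected fewer genes than VAS. Random loss of their molecules was not tested. Camera called 0 lists (at an unadjusted p under 0.05, 1 of 27 added and 0 of 5 fixed) and fry 17 added. Leaving out 1 female ended the calls of Cd163, Ms4a2, Arhgap30, Edn3 and Scube3, at adjusted p from 0.0505 to 0.128.

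Several transcripts of oocytes and of the cumulus and granulosa cells that surround them were higher in COP than in CTR oviducts. Nr5a1, a nuclear receptor of steroid-producing cells, rose from 0.455 ± 0.274 CPM (SD, n = 5) to 3.17 ± 0.802 CPM (n = 4), a log2 fold change of 2.8 ± 0.4 (SE, adjusted p = 0.000172). Its relative Nr5a2 rose from 0.351 ± 0.239 to 2.45 ± 0.399 CPM (2.81 ± 0.42, adjusted p = 0.000246). Fshr, the receptor of follicle-stimulating hormone, had no count in CTR and 0.174 ± 0.139 CPM in COP, at least 7.04-fold higher. All 3 were called among 6 tested members of the fixed cumulus and granulosa list, and 3 adjusted over the list alone. That list was higher (adjusted p = 0.000845, or 0.0224 with an estimated correlation). Of 7 oocyte markers 1 rose, and 3 adjusted over the list alone. It was Obox5, a homeobox gene of the oocyte with similar neighbours (from 0.0564 ± 0.0638 to 0.807 ± 0.231 CPM, adjusted p = 0.000792). The oocyte markers as a list were higher (adjusted p = 0.0313, or 0.29 with an estimated correlation), a call lost without female 3, 5, 6, 8 or 14 (0.057, 0.0878, 0.0606, 0.0516 and 0.0573). The added list of oocyte and early embryo genes was higher with 5 of 13 called (adjusted p = 4.47e-05, or 0.0415 with an estimated correlation). Among them were Fbxw24 (0.392 ± 0.0701 against 0.0569 ± 0.0585 CPM) and Tcl1b1 (0.205 ± 0.0695 against 0.0198 ± 0.0443 CPM), both with near copies and uncertain. The added cumulus list, which holds Nr5a1 and Nr5a2 too, was higher with 3 of 7 called (adjusted p = 0.00305, or 0.0415 with an estimated correlation), with Rhox8 at 0.874 ± 0.208 against 0.077 ± 0.0958 CPM.

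Mmp13 rose in the COP oviduct from 0.185 ± 0.135 to 2.02 ± 0.503 CPM (3.45 ± 0.64, adjusted p = 0.00144). Ms4a1, the B cell antigen CD20, rose from 0.359 ± 0.286 to 1.77 ± 0.54 CPM, 1 of 5 tested B cell markers and 1 adjusted over the list alone. Their list was higher (adjusted p = 0.0321, or 0.118 with an estimated correlation), a call lost without female 2, 3, 5 or 6 (0.0563, 0.057, 0.0695 and 0.0606). Klrb1c, a receptor of NK cells, rose by 4.23 ± 1.1 on the log2 scale, Mug1, a plasma protease inhibitor with similar copies, by 4.12 ± 0.97, Gsg1l by 3.97 ± 0.66 and Kcnab3 by 3.6 ± 0.64. Among genes that fell, Grin2a, an NMDA receptor subunit, went from 6.95 ± 2.35 to 0.589 ± 0.25 CPM (-3.55 ± 0.34, adjusted p = 3.73e-06). Reln, the secreted protein reelin, went from 5.72 ± 1.87 to 1.47 ± 0.174 CPM (-1.96 ± 0.23, adjusted p = 3.1e-05) and Cnr1, the cannabinoid receptor, from 3.09 ± 1.05 to 0.781 ± 0.0611 CPM (-1.98 ± 0.27, adjusted p = 9.8e-05). Dcx (-4.35 ± 0.92), Slc25a21 (-2.07 ± 0.46) and Slitrk3 (-1.87 ± 0.47) fell too. The list of Zfp genes was lower (adjusted p = 0.00305, or 0.0415 with an estimated correlation and 0.319 against every tested gene), with 3 of 37 members lower, among them Zfp966 (-1.2 ± 0.22) and Zfp831 (-0.98 ± 0.26), and 1 higher. Nr5a1 (ENSMUSG00000026751) lies on chromosome 2 from 38692656 to 38714542 and Obox5 (ENSMUSG00000074366) on chromosome 7 from 15750131 to 15759800. Grin2a (ENSMUSG00000059003) lies on chromosome 16 from 9567898 to 9995560 and Reln (ENSMUSG00000042453) on chromosome 5 from 21884454 to 22344702.

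In all 2212 genes were higher and 1950 lower in COP than in CTR oviducts among 20471 tested, with a median absolute log2 fold change of 0.53 and names for 113 and 61. Without control female 10 the lower count was 3575, and voom with sample weights called 3968 and 3898. Leaving out 1 female ended the calls of Tcl1b1, Fbxw24, Rhox8 and Zfp831 (without 5), at adjusted p-values up to 0.1.

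**Figure D3:**
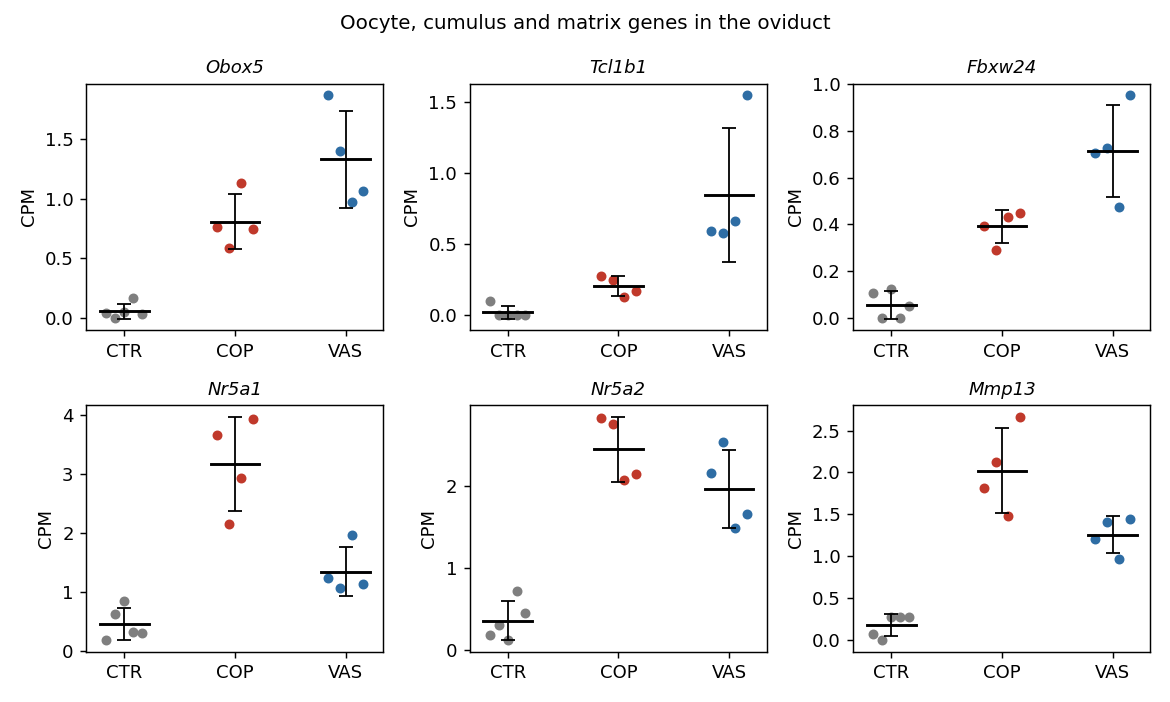
CPM of 6 genes (Obox5, Tcl1b1, Fbxw24, Nr5a1, Nr5a2 and Mmp13) in each oviduct library by treatment, with 1 point per female, the mean as a line and the SD as an error bar. Nr5a1 averages 0.455 CPM in CTR, 3.17 CPM in COP and 1.35 CPM in VAS.

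VAS oviducts showed the same kinds of genes above CTR. Obox5 rose from 0.0564 ± 0.0638 CPM (SD, n = 5) to 1.33 ± 0.405 CPM (n = 4), a log2 fold change of 4.55 ± 0.67 (SE, adjusted p = 0.000334), and Zar1, a maternal-effect gene of the oocyte, from 0.141 ± 0.128 to 0.766 ± 0.261 CPM. Padi6, another oocyte gene, had no count in CTR and was at least 14.9-fold higher (0.369 ± 0.248 CPM; adjusted p = 0.0502 without female 15). The oocyte markers were higher with 3 of 7 called, 3 also adjusted over the list alone (adjusted p = 0.00455, or 0.179 with an estimated correlation). The added oocyte list was higher with 7 of 13 called (adjusted p = 4.82e-07, or 0.0197 with an estimated correlation). Among them were Tcl1b2 (from 0.153 ± 0.109 to 1.18 ± 0.0556 CPM), Tcl1b1 (from 0.0198 ± 0.0443 to 0.845 ± 0.471 CPM) and Fbxw24 (from 0.0569 ± 0.0585 to 0.714 ± 0.195 CPM). Of 6 cumulus and granulosa markers 3 rose, also adjusted over the list alone (adjusted p = 0.00455, or adjusted p = 0.0639 with an estimated correlation). Nr5a2 stood at 1.96 ± 0.478 CPM, Nr5a1 at 1.35 ± 0.415 CPM (1.56 ± 0.4, adjusted p = 0.014, or 0.0538 without female 15) and Fshr at 0.213 ± 0.225 CPM, at least 8.64-fold higher. The added cumulus list was higher as well (adjusted p = 0.0231, or 0.123 with an estimated correlation), but not without female 1, 2 or 6 (0.0717, 0.067 and 0.0566).

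The added macrophage list was higher in VAS oviducts (adjusted p = 2.07e-05, or 0.123 with an estimated correlation), with 17 of 18 members at a higher mean, 3 called and 15 not. Among those were Cd5l, a protein secreted by macrophages (from 0.0932 ± 0.136 to 1.26 ± 0.0677 CPM, adjusted p = 0.0158) and Timd4, a receptor for phosphatidylserine (from 0.174 ± 0.169 to 1.34 ± 0.526 CPM, adjusted p = 0.0413). The neutrophil and activated myeloid list was higher (adjusted p = 0.00888, or 0.403 with an estimated correlation), with Clec5a (2.79 ± 0.72) and the hexokinase gene Hk3 (2.99 ± 0.71) called among 20. T and NK cell markers were higher with 1 of 7 called, Klrb1c (4.28 ± 1.1), and 3 adjusted over the list alone (adjusted p = 0.0381, or 0.345 with an estimated correlation). The list call was lost without female 3, 6, 7, 8, 9, 10, 13 or 14 (adjusted p = 0.0523 to 0.157). The dendritic cell list was higher (adjusted p = 0.0396, or 0.424 with an estimated correlation) with all 7 means higher, a call lost without female 3, 6, 8, 9, 10, 13 or 14 (0.0521 to 0.153). Of its members the edgeR test called 0, with 0 at an unadjusted p under 0.05, DESeq2 called 0 and voom with sample weights 2.

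F10, coagulation factor X, rose in VAS oviducts from 0.048 ± 0.0484 to 2.04 ± 0.473 CPM (5.35 ± 0.69, adjusted p = 0.000107). Gsg1l (3.3 ± 0.65) rose as well, and Mmp13 stood at 1.26 ± 0.217 CPM (2.77 ± 0.63, adjusted p = 0.00742). Grin2a fell to 0.607 ± 0.151 CPM (-3.51 ± 0.34, adjusted p = 6.63e-06) and the POU factor gene Pou3f3 from 1.04 ± 0.152 to 0.0609 ± 0.0506 CPM (-4.07 ± 0.63, adjusted p = 0.000514). Dcx (-2.68 ± 0.82), Sorcs1 (-1.96 ± 0.55), the lymphatic regulator Prox1 (-1.9 ± 0.43) and Nell2 (-1.74 ± 0.39) fell as well. F10 (ENSMUSG00000031444) lies on chromosome 8 from 13037308 to 13056676 and Pou3f3 (ENSMUSG00000045515) on chromosome 1 from 42695768 to 42703176. In all 1745 genes were higher and 1846 lower among 20471 tested, with names for 107 and 28. Without control female 10 the counts were 3142 and 3250. A fit to both groups alone called 1074 and 1185 and voom with sample weights 3705 and 3508. A single left-out female ended the calls of Zar1, Timd4, Dcx, Sorcs1 and Klrb1c (without 13), at adjusted p-values up to 0.114.

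Between COP and VAS oviducts the genes of eggs and cumulus were not called. Nr5a1, at 3.17 ± 0.802 CPM (SD, n = 4) against 1.35 ± 0.415 CPM (n = 4), missed the threshold (log2 fold change 1.24 ± 0.41, SE, adjusted p = 0.0813). The added macrophage list was lower in COP than in VAS (adjusted p = 0.014, or adjusted p = 0.346 with an estimated correlation; 0.0741 without female 5), with all 18 means lower and 1 called. Cyp2j13, an epoxygenase, was lower at 1.26 ± 0.2 against 4.04 ± 1.17 CPM (-1.68 ± 0.23, adjusted p = 0.000378) and Fat3, an atypical cadherin, at 1.43 ± 0.328 against 4.42 ± 0.8 CPM (-1.62 ± 0.26, adjusted p = 0.00139). Cacng6 (-3.4 ± 0.91), Slc25a21 (-1.85 ± 0.47), the hair keratin gene Krt35 (-1.3 ± 0.38) and Zfp966 (-1.19 ± 0.23) were lower too. Higher in COP were Opcml, a cell adhesion gene (1.64 ± 0.086 against 0.481 ± 0.194 CPM, 1.77 ± 0.33, adjusted p = 0.00352), Mro (1.65 ± 0.43), Lao1 (1.53 ± 0.38), the glutamate transporter gene Slc1a2 (1.2 ± 0.35), Kcp (1.18 ± 0.25) and Luzp2 (1.1 ± 0.27). Cyp2j13 (ENSMUSG00000028571) lies on chromosome 4 from 96027534 to 96077546 and Fat3 (ENSMUSG00000074505) on chromosome 9 from 15910189 to 16501285.

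Other lists called between COP and VAS oviducts had no member called by the edgeR test. B cell markers were higher (adjusted p = 0.0472, or 0.278 with an estimated correlation), a call lost without female 3, 5, 7, 9, 10, 13, 14 or 15 (0.0524 to 0.136). Fat cell markers were higher (adjusted p = 0.0403, or 0.278 with an estimated correlation), a call lost without 5 or 7 (0.0645 and 0.0577). Dendritic cell markers were lower (adjusted p = 0.0213, or 0.278 with an estimated correlation), a call lost without 6 (0.0636), and so were pan-leukocyte genes (adjusted p = 0.014, or 0.113 with an estimated correlation). At an unadjusted p under 0.05 these 4 lists held 1, 1, 3 and 2 members, DESeq2 called 0, 0, 0 and 1, and voom with sample weights 1, 2, 2 and 5. In all 1073 genes were higher and 833 lower in COP among 20471 tested, with names for 13 and 19. Without control female 10 the counts were 2691 and 2704. The higher count was 703 without 5, 679 without 13 and 710 without 15, and the lower count 531, 537, 525 and 554 without 5, 7, 9 and 13. A fit to both groups alone called 2412 and 2340, voom with sample weights 3224 and 2830 and DESeq2 1257 lower. Leaving out 1 female ended the calls of Slc1a2, Krt35, Cacng6, Slc25a21, Mro, Lao1 and Luzp2, at adjusted p-values from 0.0508 to 0.143.

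COP and VAS shared many of their changes against CTR in each tissue. Genes such as Grid1 and Vstm2a in the uterus, Trank1, Cd86 and Sh3rf3 in the uterotubal junction and Grin2a, Obox5 and Nr5a2 in the oviduct were called the same way in both. In the uterus 2698 genes were called in the same direction and 5 in opposite directions, in the uterotubal junction 6221 and 305, and in the oviduct 2045 and 67. Independent lists of these sizes would share 173.4 higher and 256.7 lower genes in the uterus, 1144.4 and 963.7 in the uterotubal junction and 188.6 and 175.8 in the oviduct. The numbers found were 1264 and 1434, 3322 and 2899, and 1103 and 942. Both comparisons share controls. With unchanged simulated groups a mean of 0 genes was shared in 20 simulations per tissue. The simulations hold no real effects and do not measure all that shared controls add. With controls split between comparisons, a mean of 1511, 4928 and 1198 genes was shared in 20 splits. The correlation of fold changes across genes, which are not independent replicates, was 0.807, 0.711 and 0.703, against 0.435, 0.43 and 0.433 in the simulations and 0.408, 0.415 and 0.368 with split controls. The covariance was 1.25, 1.79 and 0.493, or 0.963, 1.58 and 0.409 with split controls. Less the simulated 0.205, 0.302 and 0.149, the former was 1.05, 1.49 and 0.344. In the uterus the shared count was 5904 without control female 12, 1614 to 1789 without COP female 5, 7 or 8 or any 1 VAS female, 970 in fits to pairs of groups alone and 7415 by voom, and in the oviduct 3650 without control female 10 and 4092 by voom.

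In unmated females, several genes of cytotoxic lymphocytes were higher in the uterus than in the junction. Prf1, which encodes perforin, stood at 1.92 ± 1.22 CPM (SD, n = 5) in the uterus and 0.184 ± 0.21 CPM (n = 5) in the junction, a log2 fold change of 3.38 ± 0.78 (SE, adjusted p = 0.000582). Eomes, a T-box factor of NK and cytotoxic T cells, stood at 1.09 ± 0.521 CPM against no count, at least 45.8-fold higher (adjusted p = 1.05e-05). Klra4, an NK receptor gene in a cluster of near copies and so uncertain, was at least 30.5-fold higher. Of 9 T and NK cell markers 3 were higher, also adjusted over the list alone (adjusted p = 0.0405, or 0.282 with an estimated correlation), a call lost without female 3, 10 or 12 (0.0537, 0.187 and 0.0863) and with the female as a block (0.0742). In the added list 14 of 41 were higher (adjusted p = 0.000191, or 0.221 with an estimated correlation). All 3 tested genes of the complement and antimicrobial list were higher, also adjusted over the list alone, among them Saa1 (at least 20.4-fold) and Bpifb1 (at least 24.3-fold), both without a count in the junction. That list call (adjusted p = 0.0405, or 0.235 with an estimated correlation) was lost without female 1, 3, 10 or 12 (0.0631, 0.0681, 0.172 and 0.0863) and with the female as a block (0.0508). Against every tested gene, no list was called between any CTR tissues.

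Col22a1, a collagen, Eya1, a factor of organ development, Iqsec3 and Nrap, a muscle anchor protein, had no count in CTR junctions and were at least 80.5-fold, 72.7-fold, 46.6-fold and 46.2-fold higher in the uterus. CTR junctions detected 17447 to 18308 genes, uteri 18239 to 21016 and oviducts 18206 to 22807. Random loss of molecules in junctions was not tested here. Drd1 was lower in the uterus, at 0.142 ± 0.104 against 3.35 ± 0.758 CPM (-4.54 ± 0.61, adjusted p = 2.46e-07), and so was Sh3rf3, at 0.533 ± 0.369 against 4.95 ± 1.35 CPM (-3.21 ± 0.56, adjusted p = 1.54e-05). The muscle genes Myom2 (-6.87 ± 1.71) and Lmod3 (-5.78 ± 1.48) and Cyp4f40 (-3.89 ± 1.1) were lower too. In all 6772 genes were higher and 3511 lower in the uterus among 22274 tested, with names for 771 and 200 of 3702, or 452 and 84 with the female as a block. Eomes (ENSMUSG00000032446) lies on chromosome 9 from 118478212 to 118486132.

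Against the CTR oviduct, several named genes had no count in CTR junctions. Of these, Frmpd4, Gpr37, the synaptic genes Lrrtm4 and Rims2, and Frem3 had 4.13 ± 1.09, 3.79 ± 0.901, 3.09 ± 0.601, 2.97 ± 0.341 and 2.66 ± 0.287 CPM (SD, n = 5) in the oviduct. They were at least 173-fold, 159-fold, 130-fold, 125-fold and 112-fold lower, and random loss was not tested. Nr5a1 was at least 17-fold lower and Pax5, a B lineage factor, stood at 0.0304 ± 0.0679 against 1.61 ± 0.373 CPM. Protocadherins and related genes were lower in the junction with 8 of 19 called (adjusted p = 0.0097, or 0.0228 with an estimated correlation and 0.054 without female 10). Among them were Dchs2 (-5.84 ± 0.95), Fat3 (-6.42 ± 1.12) and Fat4 (-2.04 ± 0.31). Macrophage genes of the added list were higher relative to other named genes with 6 of 19 called (adjusted p = 0.000217, or 0.0228 with an estimated correlation and 0.334 against every tested gene). Tlr7, a receptor of single-stranded RNA, stood at 1.7 ± 1.01 against 0.287 ± 0.223 CPM (2.56 ± 0.6, adjusted p = 0.000509). Has2 (3.61 ± 0.8), Cyp1a1 (3.53 ± 0.72), Rnf224 (3.51 ± 1.18) and the gasdermin gene Gsdmc (4.17 ± 1.61) were higher in the junction, the call of Gsdmc not without female 1, 3 or 10 (adjusted p = 0.0927, 0.0572 and 0.0661). Pan-leukocyte genes, with 2 higher and 3 lower of 20, were called higher only with the female as a block (adjusted p = 0.0432 against 0.0932). In all 4731 genes were higher and 6957 lower among 22274 tested, with names for 147 and 1162, or 67 and 852 with the female as a block. Rims2 (ENSMUSG00000037386) lies on chromosome 15 from 39198261 to 39684372 and Tlr7 (ENSMUSG00000044583) on chromosome X from 167304929 to 167330558.

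CTR uterus and CTR oviduct differed in several leukocyte genes. Eomes stood at 1.09 ± 0.521 CPM (SD, n = 5) in the uterus and 0.0352 ± 0.0609 CPM in the oviduct (log2 fold change 4.9 ± 1.18, SE, adjusted p = 0.000789). Prf1 was higher by 2.69 ± 0.75 and Klra4 at least 32.9-fold higher. The T and NK markers were higher with 2 of 9 called, also adjusted over the list alone (adjusted p = 0.00634, or adjusted p = 0.172 with an estimated correlation; 0.121 without female 10), as was the added list with 8 of 41 called (adjusted p = 5.34e-05, or adjusted p = 0.0506 with an estimated correlation). Pan-leukocyte genes were higher with 7 higher and 1 lower of 20 (adjusted p = 0.00023, or adjusted p = 0.0506 with an estimated correlation), and macrophage genes with 4 higher and 1 lower of 19 (adjusted p = 0.0118, or adjusted p = 0.11 with an estimated correlation). The neutrophil list, higher at an adjusted p of 0.0174 (0.416 with an estimated correlation), was not called without female 12 (adjusted p = 0.246), whose uterus library stood apart. Pck1, an enzyme of gluconeogenesis (5.1 ± 1.34), the nuclear receptor gene Rorb (5.11 ± 1.18), Mgam (5.36 ± 1.33), Iqsec3 (5.8 ± 1.74) and Nrap (6.93 ± 1.36) were higher in the uterus. Cyp2j13, Gal3st2c, Pramel3, Glb1l3 and the anion exchanger gene Slc26a3 had no count in CTR uteri and were at least 168-fold, 160-fold, 126-fold, 116-fold and 108-fold lower than in the oviduct. So was Lhx1, a factor of duct patterning, at least 14.8-fold lower. Protocadherins and related genes were lower in the uterus with 7 lower and 1 higher of 19 (adjusted p = 0.00169, or 0.0224 with an estimated correlation), such as Dchs2 (-4.78 ± 0.89) and Pcdh11x (-1.84 ± 0.31). Matrix genes, with 9 higher and 5 lower of 38, were called higher only with the female as a block (adjusted p = 0.028 against 0.0555). In all 6272 genes were higher and 5865 lower in the uterus among 22274 tested, with names for 311 and 725, or 161 and 511 with the female as a block. Pck1 (ENSMUSG00000027513) lies on chromosome 2 from 173153048 to 173159273 and Slc26a3 (ENSMUSG00000001225) on chromosome 12 from 31390871 to 31473917.

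Whether copulation changed genes differently along the tract was tested directly, on libraries of all 3 tissues scaled together, so that CPM differ a little from those of 1 tissue. Fat4, an atypical cadherin, went after mating with intact males from a mean of 0.683 to 4.09 CPM in the uterotubal junction. It was at 2.01 CPM in CTR and 1.09 CPM in COP uteri, and the changes differed by -3.46 ± 0.47 (log2, SE, edgeR adjusted p = 1.77e-06). The same held for Ago3, an Argonaute protein, at 1.3 CPM in CTR and 5.37 CPM in COP junctions against 6.15 and 7.08 CPM in uteri (-1.85 ± 0.3, adjusted p = 3.7e-05) and for Srrm4 (-2.75 ± 0.53). Smarca1 fell in the uterus from 3.36 to 0.563 CPM, against 1.62 and 2.54 CPM in the junction (-3.22 ± 0.47, adjusted p = 6.37e-06), and Tet1, an enzyme of DNA demethylation, from 3.85 to 0.746 CPM against 1 and 1.87 CPM in the junction (-3.27 ± 0.53). Between junction and oviduct, Fat4 (2.6 ± 0.46) and Ago3 (2.35 ± 0.31) differed again, as did Abcd2, which had no count in CTR junctions and 0.519 CPM in COP. Has2 and Gsg1l went to no count in COP junctions, while Gsg1l was at 0.116 CPM in CTR and 1.81 CPM in COP oviducts. Between uterus and oviduct, Smarca1 (-3.49 ± 0.47, adjusted p = 1.82e-06), Tet1 (-2.61 ± 0.53), Efr3b (-2.44 ± 0.59), the mechanosensitive channel gene Piezo2 (5.15 to 1.55 CPM in the uterus, 3.89 to 8.67 CPM in the oviduct, -2.88 ± 0.55) and Cemip, which acts in hyaluronan breakdown (2.19 to 1.04 CPM and 1.11 to 5.48 CPM, -3.37 ± 0.7), differed.

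After mating with vasectomized males Fat4 and Ago3 again differed between uterus and junction (-3.27 ± 0.46 and -2.1 ± 0.31) and between junction and oviduct (2.66 ± 0.46 and 2.56 ± 0.31). Pcdh11x (-2.92 ± 0.47), Abca8a (-3.12 ± 0.52) and Arhgap20 (-1.72 ± 0.3) differed between uterus and junction. Rims2, Ccdc177 and Egf, the epidermal growth factor, had no count in CTR junctions and reached 0.358, 0.631 and 0.738 CPM in VAS, against changes from 2.97 to 2.43, 2.53 to 2.66 and 1.87 to 1.37 CPM in the oviduct. Smarca1 (-3.5 ± 0.47), Piezo2 (-2.83 ± 0.55), Cemip (-3.53 ± 0.7), Pcdh11x (-2.34 ± 0.47) and Tmem229a (-1.98 ± 0.43) differed between uterus and oviduct. Fat4 (ENSMUSG00000046743) lies on chromosome 3 from 38886940 to 39011985 and Ago3 (ENSMUSG00000028842) on chromosome 4 from 126331704 to 126429556.

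For COP minus CTR, 4796 genes differed in their change between uterus and uterotubal junction, 3496 between junction and oviduct and 3554 between uterus and oviduct, and for VAS minus CTR 3905, 4499 and 3518, all of 22274 tested. In VAS the difference between junction and oviduct was higher for 3114 genes and lower for 1385, a share of 69.2% higher, which was 58.9% with RLE scaling (2631 and 1836) and 57.5% with DESeq2. Without female 5, 7, 8 or 9 the COP count between junction and oviduct was 2308, 2206, 2138 or 2188. In VAS the counts were 2542, 2771 and 2306 without 15, and the last 2263 without 13. Without the doubted libraries of females 12 and 10, the COP counts with the oviduct were 5492 and 5857, and the VAS counts with the uterus 5949 and 5574.

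**Figure D4:**
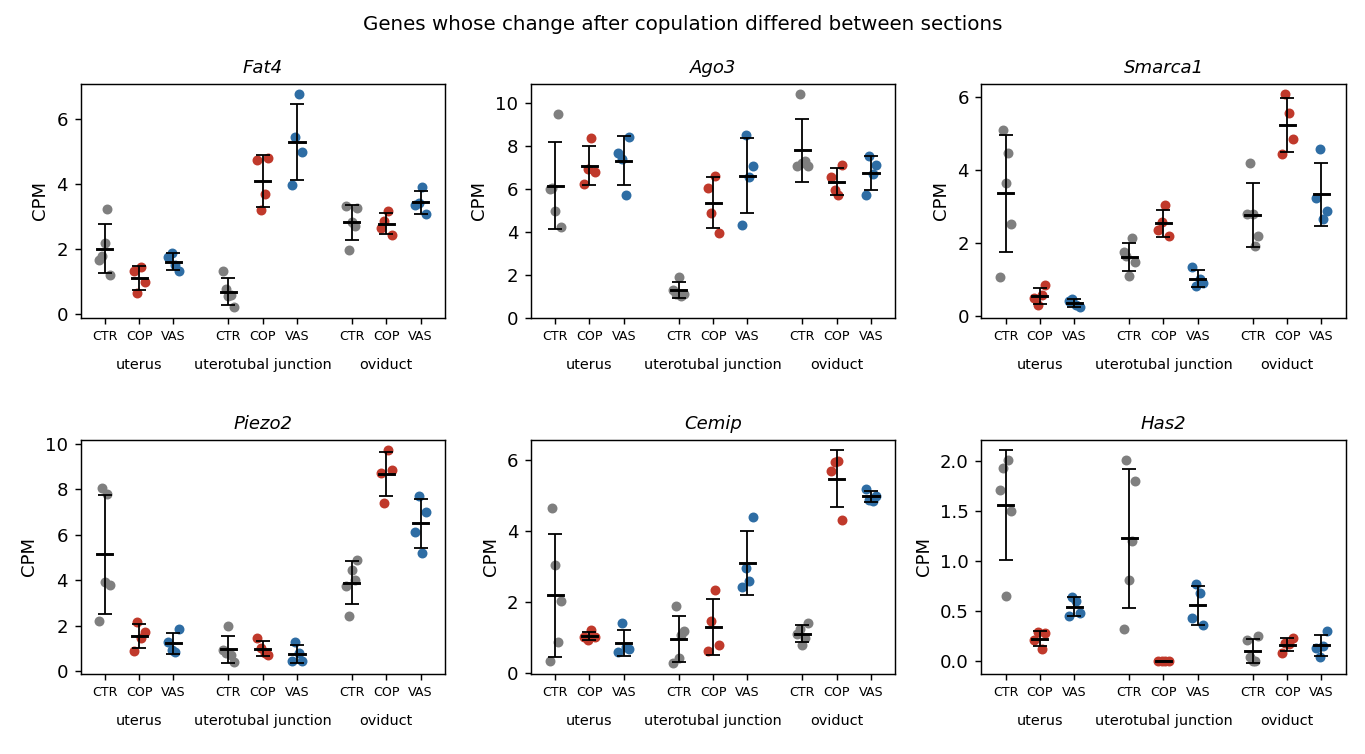
CPM of 6 genes (Fat4, Ago3, Smarca1, Piezo2, Cemip and Has2) in all 39 libraries by tissue and treatment, with 1 point per female, the mean as a line and the SD as an error bar. Fat4 averages 0.683 CPM in CTR junctions and 4.09 and 5.27 CPM in COP and VAS junctions.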

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

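All tests of the patterns weighed below were chosen after the results were seen, except the splits of the samples and the list test without control female 10, 1 of the planned fits that left out each female in turn.

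More named genes were higher than lower in mated uterotubal junctions, 209 against 110 in COP and 250 against 18 in VAS. Random loss of molecules from control libraries would leave the summed CPM of 5302 named genes under 1 CPM alike. In VAS these sums were 1.482 times the CTR sums with TMM scaling and 1.452 times without (two-sided exact permutation p = 0.0159 each, the smallest possible), which argues against it. In COP the ratio was 1.168 with TMM scaling, on which a first test alone rested, and 0.939 without, so such loss cannot be told apart there from a change in the genes. With every library thinned to the number of pairs in the shallowest one, a median of 91 genes was higher and 40 lower in COP and 121 and 16 in VAS over 5 thinnings, which argues against depth, while reads from unspliced RNA or DNA were not tested and, like a response to mating, stay open.

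Control uteri stood apart from each other, above all the library labelled female 12, where genes of the oviduct reached a median 0% of their control oviduct level, at or below the 0.188% to 0.814% of the other CTR uteri, which argues against oviduct tissue. Mated uteri of similar total (142520954 and 143333002 counts against 141502233) stood 0.068 and 0.132 from their groups against 0.848, which argues against depth, though its total was the highest of the 5 CTR uteri. A mated uterus under that label cannot be told apart from other sources: the median position of 0.833 between CTR (0) and mated uteri (1) may point to one, while its distance of 0.633 to COP uteri, above the largest of 0.133 within COP, points away, and a first test on distance alone had argued against a wrong label. No mated uterus was out of place (0.132 or less), so a swap has no partner, but a single wrong label needs none. The CTR uterus of female 1 lay partway (0.433), and differences in cycle stage between control females were not tested.

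The fixed and added lists of oocyte and cumulus genes were called higher in mated oviducts. With an estimated correlation the fixed oocyte list (adjusted p = 0.29 in COP and 0.179 in VAS) and, in VAS, the fixed and added cumulus lists (0.0639 and 0.123) lost the call. Low complexity of the CTR library of female 10 is argued against for the added oocyte list, which stayed higher without it at an adjusted p of at most 0.000118. Cumulus-oocyte complexes in mated oviducts are a candidate source that stays open, as in mated uteri no oocyte list was called (smallest adjusted p = 0.796 for the fixed and 0.843 for the added list) while the added cumulus list was lower (0.00436 in COP and 0.0389 in VAS, or 0.15 and 0.175 with an estimated correlation). A difference in the time since ovulation between mated and CTR females was not tested.

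In splits of libraries into groups of the same sizes, 2 of 100 called as many genes for COP against CTR in the uterus (4394), which does not exclude chance. The other (6258) sets females 1, 2, 3 and 10 against the rest and leaves 12 with the mated. It was 1 of 100 for VAS against CTR in the uterus (3795, highest other 2985), for COP and VAS against CTR in the uterotubal junction (8944 and 5694, 8800 and 5767) and in the oviduct (4162 and 1792, 3591 and 1461). Ranks were not adjusted over patterns. COP against VAS called 90, 5478 and 1906 genes in uterus, uterotubal junction and oviduct, 1 of 35 splits each, with 0, 52 and 0 as the highest other. For the change in COP between tissues, 1 of 100 splits called as many between uterus and uterotubal junction (4796, highest other 4244) and between uterotubal junction and oviduct (3496, highest other 1351), and 2 of 100 between uterus and oviduct (3554, highest other 3769). In VAS it was 1 of 100 each (3905 and 3729, 4499 and 2144, 3518 and 3400). Between CTR tissues, 1 of 100 splits each called as many genes, 10283 (highest other 6262) for uterus and junction, 11688 (3447) for junction and oviduct and 12137 (6666) for uterus and oviduct. As the libraries of a female pair across tissues, the 16 splits that part every pair bear most on this. Among them the real split was again the only one as large, with 6141, 3349 and 6666 as the highest other. The others mix tissues within each side, and with the female as a block 5393 and 3274 genes differed between uterus and junction.

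Chance sets a library apart in about 1 in 20 groups, and 7 of 54 groups of library measures and 44 of 414 groups of gene values held one. For library measures these were the share of the 10 most abundant genes in the CTR uterus of female 12 (15.55%) and the CTR oviduct of female 10 (11.18%), the genes detected in the CTR oviduct of female 10 (18206) and the COP junction of female 8 (18100), the total of the COP junction of female 5 (85213185 counts), and the distance to the group of the latter library (0.24) and of the CTR oviduct of female 10 (0.625).

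Values in CPM far from the other females of the group were, in CTR uteri, those of female 10 for Cpvl (0.362), Iqsec3 (2.98), Rasl10b (0.867), Vstm2a (2.79), Asz1 (0.171), Col22a1 (5.79) and Eomes (1.99). Others there were those of female 1 for Nlrc3 (0.234), Nrap (2.06) and Cyp4f40 (0.344), female 2 for Casq2 (1.29) and Lmod3 (0.102), female 3 for Zfp786 (1.72) and Myom2 (0.0534) and female 12 for Treml2 (2.75). In VAS uteri it was Tmem229a (0.203) in female 14. In CTR junctions they were Adra2b (0.362) and Nfasc (2.65) in female 10, Luzp2 (0.331) and Kif1a (0.624) in 1, Nav3 (0.168) and Fat3 (0.18) in 12, Fcer2a (0.735) and Tcp10c (0.302) in 2, and Pax5 (0.152) in 3. In mated junctions they were Cd8a (0.231) in COP female 9 and Arhgap30 (3.96) in COP 5, and Abca6 (3.3) and Sh3rf3 (0.785) in VAS 13, Cd8a (0.168) in VAS 15 and Vstm2a (0.187) in VAS 6. In CTR oviducts they were Hk3 (0), Prox1 (4.59) and Ago3 (10.4) in female 10, Klrb1c (0.27) and Nrap (0.0404) in 12, Obox5 (0.166) and Iqsec3 (0.0968) in 2, Tcl1b1 (0.0992) in 1 and Eomes (0.141) in 3. In mated oviducts they were Fshr (0.381) in COP female 8, Cyp2j13 (1.56) and Cemip (4.31) in COP 9 and Tcl1b1 (1.55) in VAS 6.

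Changes that differed between tissues by the edgeR test were, in log2 units for COP between uterus and junction, those of Fat4 (-3.46), Smarca1 (-3.22), Tet1 (-3.27), Ago3 (-1.85) and Srrm4 (-2.75). Between junction and oviduct they were Fat4 (2.6), Ago3 (2.35), Abcd2 (7.58), Has2 (-10.73) and Gsg1l (-10.94), and between uterus and oviduct they were Smarca1 (-3.49), Tet1 (-2.61), Efr3b (-2.44), Piezo2 (-2.88) and Cemip (-3.37). For VAS they were Fat4 (-3.27), Ago3 (-2.1), Pcdh11x (-2.92), Abca8a (-3.12) and Arhgap20 (-1.72) between uterus and junction. Between junction and oviduct they were Fat4 (2.66), Ago3 (2.56), Rims2 (8.53), Ccdc177 (9.0) and Egf (9.74), and between uterus and oviduct Smarca1 (-3.5), Piezo2 (-2.83), Cemip (-3.53), Pcdh11x (-2.34) and Tmem229a (-1.98). Values beyond 7 involve a group with no count and are fitted values, not sizes.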

How the results depend on the processing

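Fits without the doubted libraries of females 12 and 10, the list background of every tested gene and the block in list tests were chosen after seeing the data. Of 808 alternative values for 41 counts and other main results, 674 stayed within 1.5 times and kept their direction and 134 did not. For 248 results of genes written out in the text 4594 of 5027 kept their call, 415 lost it, 17 gained one and 1 turned, Cd8a in COP against CTR junctions, whose log2 fold change ran from 0 without female 9 to 6.07 without 5. Called lists kept 527 of 657. An alternative with a score of the fixed neutrophil list as covariate was not run, because no member of that list, which is not the added list of neutrophils and activated myeloid cells, was tested. Where no cause is given, the cause was not tested.

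Fits to the compared groups alone gave 744 higher and 1232 lower for COP against CTR, 779 and 831 for VAS against CTR and 3805 and 4098 for COP against VAS in the uterus, 1074 and 1185 for VAS against CTR and 2412 and 2340 for COP against VAS in the oviduct. Voom with sample weights gave 4633 and 4614, 4404 and 4568, and 3780 and 4008 in the uterus and 3968 and 3898, 3705 and 3508, and 3224 and 2830 in the oviduct. DESeq2 called 3017 lower in VAS against CTR and 244 and 409 in COP against VAS uteri, and 1257 lower in COP against VAS oviducts. For COP against VAS uteri no filter gave 23 higher and a stricter one 81 lower. Without both doubted libraries the counts were 3824 and 3990, 3565 and 3794, and 337 and 707 in the uterus, 3575 lower, 3142 and 3250, and 2691 and 2704 in the oviduct, and for changes between tissues 5492 and 5857 in COP and 5949 and 5574 in VAS.

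Leaving out 1 female gave 1195 to 3824 higher and 1454 to 3990 lower for COP against CTR, 1082 to 3565 and 1043 to 3794 for VAS against CTR and 6 to 337 and 12 to 707 for COP against VAS uteri. In the oviduct it gave 1306 to 3575 lower for COP against CTR, 1214 to 3142 and 1260 to 3250 for VAS against CTR and 679 to 2691 and 525 to 2704 for COP against VAS. The highest values were those without control female 12 or 10. Changes between tissues ran from 2138 to 4566 (junction and oviduct) and 2412 to 4977 (uterus and oviduct) in COP and from 2542 to 5132, 2771 to 5352 and 2263 to 4952 in VAS.

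Of fixed lists 13 were called, 3 against every tested gene, 1 with an estimated correlation, 42 by fry, and 6 to 13 without 1 female, with 6 without female 3 and 8 without 6. Of added lists 25 were called, or 9, 7 and 168. Sperm transcripts, called in no comparison, changed sign as the number of list genes with a count (0.1 for COP minus CTR in the junction, -0.5 for COP minus VAS in the oviduct) and without 1 female. The differences in CPM then ran from -0.0999 to 0.0414 for COP minus VAS uteri (above 0 without 15), from -0.113 to 0.0254 for COP minus CTR junctions (above 0 without 1) and from -0.0415 to 0.398 for COP minus VAS oviducts (below 0 without 6). Genes shared by COP and VAS numbered 970 in fits of groups alone, 7415 by voom, 5904 without doubted libraries, 1511 with split controls and 1614 to 5904 without 1 female in the uterus, and 4092, 3650, 1198 and 1603 to 3650 by the last 4 of these in the oviduct.

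With the female as a block, counts of all genes between tissues stayed within 1.5 times (5393 and 3274, 4379 and 6358, 5485 and 5473), and several counts of named genes fell by more, as from 771 and 200 to 452 and 84 between uterus and junction. The 75 single-gene results fitted with the block kept their call. The block ended 2 list calls between uterus and junction, T and NK markers (adjusted p = 0.0742) and complement genes (0.0508). It gained 2, pan-leukocyte genes between junction and oviduct (0.0432) and matrix genes between uterus and oviduct (0.028), and changed no other list call. RLE and DESeq2 moved no median of all genes by over 0.1 from TMM (largest shift -0.082). Without TMM the sum of low named genes in COP junctions was 0.939 times that in CTR, not 1.168. At this depth most named genes hold few counts, and a gene that was not called is not shown to be unchanged.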

Other observations

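Transcription factors of embryonic patterning, a group added after the identifiers were seen, held 4 of 20 tested members that fell in both mated uteri, while the list was not called (adjusted p = 0.147 in COP and 0.254 in VAS). Eya1, which acts in organ formation, went from 1.69 ± 0.741 CPM (SD, n = 5) in CTR to 0.386 ± 0.168 CPM (n = 4) in COP and 0.28 ± 0.138 CPM (n = 4) in VAS, log2 fold changes of -2.13 ± 0.47 (SE, adjusted p = 0.00736) and -2.59 ± 0.48 (adjusted p = 0.00347). Dach2 fell to 0.302 ± 0.0879 and 0.366 ± 0.0473 CPM from 1.21 ± 0.473 CPM, and Gli3, a mediator of hedgehog signalling, to 1.35 ± 0.124 and 1.22 ± 0.293 CPM from 4.13 ± 2.36 CPM. Rorb fell to 1.37 ± 0.541 and 1.23 ± 0.185 CPM from 4.28 ± 2.81 CPM, but not without female 2, 5, 7, 9 or 10 in COP (adjusted p = 0.0502, 0.0836, 0.0544, 0.085 and 0.0589) or without 6, 13, 14 or 15 in VAS (0.0545, 0.0671, 0.0565 and 0.0691).

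In the uterotubal junction Muc3a, a membrane mucin, had no count in CTR and stood at 0.787 ± 0.236 CPM in COP and 0.777 ± 0.29 CPM in VAS, at least 35.2-fold and 34.8-fold higher. Fat4 rose there from 0.641 ± 0.384 CPM to 3.67 ± 0.72 CPM in COP and 4.72 ± 1.03 CPM in VAS (log2 fold changes 2.51 ± 0.39 and 2.88 ± 0.39). In the oviduct Aqp9, a channel for water and glycerol, rose from 0.0331 ± 0.0454 CPM to 0.404 ± 0.276 CPM in COP (adjusted p = 0.0285, but 0.0772, 0.0899 and 0.0501 without female 5, 8 or 12) and 0.515 ± 0.207 CPM in VAS (adjusted p = 0.0215, but 0.0541 and 0.0509 without 6 or 14). Slc26a3, a chloride and bicarbonate exchanger, fell in COP oviducts from 2.28 ± 0.49 to 1.01 ± 0.269 CPM (adjusted p = 0.0136, or 0.0508 without female 9).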
